A study of Saccharomyces cerevisiae with 50 samples.

How the data were processed

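Ribosome footprints and total mRNA were sequenced from 25 SK1 yeast strains, 50 libraries in all. The 2 wild-type samples share the strain number 4484 and are counted as 2 strains throughout. Cells were grown in rich medium with 2% glucose at 30 °C and collected at an OD600 of 0.6. Per the labels' protocols, cells were flash frozen, then milled cold for footprints or extracted with hot acid phenol for mRNA. The submitters' processing notes name CASAVA, bcl2fastq 2.17 and Bowtie2, with no order. The genome build, the annotation, the treatment of reads that match several genes and the use of strand are not given in the sources used here.

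The authors deposited 1 table per assay with 25 columns headed RPKM. The deposited values behaved as a signal that grows with gene length, not as RPKM. In every library, 1 read of a gene was worth a constant times the coding length less 60 nt, so that reads scaled to the library total had been multiplied by a length term. The dynein gene DYN1 had a mean deposited mRNA signal of 1373.8 and TDH3 one of 6905.9, against 27.6 and 23497 RPKM after recomputation. Whole reads were recovered from the steps of the values, within a tolerance of 0.03 reads. Of 5812 open reading frames with an annotated length and any signal, 87.6% gave whole reads in every library at that length, against 21 of 5805 at the length of another gene drawn at random. Of 6679 open reading frames, 5994 matched the gene table of the R64 reference, which was used only for names, chromosome and coding length. For 5090 the annotated length gave whole reads, for 994 the length was found from the values, 351 were at 0 in all libraries, and 244 without a length were left out. A length found from the values gives whole reads by construction, so it is no evidence for the recovery, and 697 of the 5103 genes tested in mRNA and 557 of the 4222 in footprints had such a length. These 244 held 0.000302% of the mRNA signal and 6.33e-05% of the footprint signal. An unnamed line of column totals was left out of each table (1 per table).

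RPKM was recomputed from the recovered reads and the coding length less 60 nt. The design fixed before the data were examined assumed that the deposited columns were RPKM, and this recomputation is the departure from it. Recovered totals were 0.962 to 3.506 M reads (M, 1000000 reads) per mRNA library and 4.102 to 8.572 M per footprint library. Totals of this size leave lowly expressed genes with few reads, and limits given for a count of 0 (3 reads) cover counting error only. RPL41A and RPL41B, which are very short, had no footprint reads in any library, and the reason was not tested.

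Strains were grouped by label into RPL strains (14), RPS strains (9) and wild type (2). Each strain had 1 library per assay. The strains of a class carry different genotypes, except for 2 RPS strains labelled rps22a (4662v and 4659). Several of them share a deleted gene, such as rpl26a rpl26b with rpl26a and with rpl26b, and rps25a rps25b with rps25b. The p-values measure the spread between strains, with the 2 wild-type samples of strain number 4484 counted as strains. The tests treat related strains as independent. Nothing in the labels says whether the wild-type libraries came from separate cultures. Their mRNA reads differed by more than counting error (chi-square per degree of freedom 3.3), as did their footprints (10.6). The assays were paired by strain number. Footprint and mRNA deviations of a strain correlated at 0.28 to 0.87 over 2708 genes in 24 of 25 strains, and at -0.12 in the strain labelled rpl26a/+ rpl26b/+. The own mRNA library ranked first for 22 of 25 footprint libraries. Those labelled rpl41a (own 0.747) and rps22a (4662v) (own 0.643) correlated more with rpl41b mRNA, at 0.781 and 0.684. The labels give no batch.

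Genes with a mean of at least 10 RPKM over the 25 libraries of an assay were tested with limma 3.58.1 in R 4.3.3 (moderated with a mean-variance trend) on log2(RPKM + 1), with the 3 classes in 1 fit, two-sided, at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(RPKM + 1) scale, where the added 1 shrinks ratios between low levels. As means of logs they can also exceed the change of the mean levels. MIN6 mRNA, for example, had means of 13.1 RPKM in RPS and 22.8 in RPL strains and a fold change of 3.37. Translational efficiency was the footprint minus the mRNA value of the same strain on that scale, which keeps the strain as a block, for genes that passed the minimum in both assays. Voom, also from limma, was run on the recovered reads as an added alternative.

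The tests, the 25 gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took the 10 largest rises and the 10 largest falls among genes past the test (5 each way for translational efficiency) with at least 75% of the strains of the first class on the called side of the median of the second class. Up to 4 members past the test were named per list, and families deleted in any strain and marker genes were reported apart. RPL8A, RPL15A and the other ribosomal protein genes named belong to families not deleted in any strain. GPM1, PRE5, RPS9B, RPS3, ATP14, MRPL16 and TIF4631 are named across assays because list or gene rules named them in at least 1 assay, and their side-by-side reading was chosen after the values were seen.

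The lists were 60S and 40S ribosomal protein genes, mitochondrial ribosomal protein genes, 40S and 60S assembly factors, RNA polymerase I, initiation factors, elongation and termination factors, ribosome-associated chaperones and rescue factors, amino acid synthesis under Gcn4, the induced environmental stress response, Hsf1-dependent chaperones, the proteasome, the unfolded protein response, glycolysis and fermentation, oxidative phosphorylation, the tricarboxylic acid and glyoxylate cycles, ergosterol synthesis, the iron, phosphate and purine genes, core histones, mating genes, early meiotic genes and strain marker genes. The Hsf1 list also holds MBF1, which is not a chaperone. HSP42, HSP104, HSP78, HSP26 and SSA4 stand in both the stress response and the Hsf1 list. The names DBP4, MDN1, EFL1, LTN1, FKB2 and MET15 found no match. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, with camera at an estimated correlation and fry as alternatives. In footprints and translational efficiency 23 lists had measured members.

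Per-strain values were the difference of the median log2 levels of 60S and 40S protein genes, the medians of 3 gene groups against the mean of the wild-type libraries, the number of genes changed by 1 or more in log2, and the median of each chromosome (a shift of 0.3 in both assays was listed). Class differences were tested by exact permutation over 817190 splits and correlations by 100000 permutations, adjusted over the 6 relations. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

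The procedures were tested on simulated data with 200 genes changed. Noise was drawn independently for each gene, library and assay. The simulation thus left out any shared variation of genes or of the assays of a strain, and its shares, false calls included, hold for independent noise only. For mRNA, RPS against RPL strains (5103 genes), 88.1%, 95.5% and 95.5% of genes changed by 0.58, 1 and 2 were recovered, and 6.5% of calls were false. For footprints (4187 genes) the shares were 88.1%, 94.0% and 95.5% with 10.6% false, and for translational efficiency (4180 genes) 61.2%, 91.0% and 95.5% with 4.6% false. The chromosome step, on 5103 genes, recovered 2 of 2 shifted chromosomes and listed 0 others.

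Alternatives fixed in advance were pseudocounts of 0.1 and 10, no minimum level and a minimum of 50 RPKM, median-of-ratios scaling, quantile normalization, scaling without ribosomal protein genes, moderation without a trend, array weights, only the 2 classes compared in the fit, removal of double heterozygotes, of strains with a listed chromosome and of each library in turn, no strain block, list tests by other methods, means for medians, and all ribosomal protein genes kept. Alternatives chosen after seeing the data were the deposited values, voom, removal of the libraries labelled rpl26a/+ rpl26b/+ (footprints), rps22a (4662v) and rps25a rps25b, 2 further forms of the 60S to 40S balance, score relations within RPS strains without rps25a rps25b, and genes changed per strain with the reads of every library thinned to the smallest total.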

Results

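Ribosome footprints and total RNA were sequenced from budding yeast strains that lacked genes for cytosolic ribosomal proteins. Yeast carries most ribosomal protein genes as a pair of paralogs (A and B copies), so that many of these genes can be deleted singly without loss of viability. The strains were of the SK1 background and were grown in rich medium with 2% glucose at 30 °C to an optical density of 0.6. The stated purpose was to find changes in gene expression linked to the overall level of translation, and the series contrasts deficiencies of the large (60S) and the small (40S) ribosomal subunit.

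The 50 libraries came from 25 strains, with the wild type, sampled under 1 strain number (4484), counted as 2. Each had 1 footprint library and 1 mRNA library. By their labels, 14 strains carried deletions of genes of the 60S subunit (RPL strains), 9 of genes of the 40S subunit (RPS strains), and 2 were wild type. The RPL class held 10 strains with 1 deleted gene, 1 strain with both paralogs deleted and 3 double heterozygotes, and the RPS class held 7, 1 and 1. Strains of a class had different genotypes, except that 2 RPS strains (4662v and 4659) were both labelled rps22a. Several others shared a deleted gene, such as rps25b and rps25a rps25b. Errors given for a class are spreads between strains (SD). Reads assigned to genes ranged from 0.962 to 3.506 M (M, 1000000 reads) per mRNA library, with medians of 2.0 M in RPL strains and 1.241 M in RPS strains. The footprint libraries held 4.102 to 8.572 M reads.

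The deleted genes were read first, in their own strains. Of 40 homozygous deletion values (20 gene and strain pairs in mRNA, 18 in footprints, and the pair of values of the strain labelled rps22a (4662v)), 38 lay below the range of all strains labelled for other gene families. Where they lay below it, the level was at most 3.05% of the median of those strains. RPL38 in rpl38 stood at 0.23% in mRNA and 1.26% in footprints, RPS0B in rps0b at 0.4% and 2.73%, and RPS25A in rps25a rps25b at 0.73% and 0.44%. RPL41A and RPL41B had 0 mRNA reads in their own strains, which with so few reads allows up to 42.3% and 14% of the usual level, and no footprint reads of either gene were assigned in any strain.

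Paralogs of the deleted genes mostly stayed within the range of the other strains, with rises in 3 families. RPL7B, normally the minor copy, was at 986% of the other strains' median in rpl7a mRNA and 846% in footprints. In the double heterozygote rpl7a/+ rpl7b/+, RPL7A was at 66.7% and RPL7B at 423% in mRNA. RPS22B reached 391% in mRNA and 491% in footprints of the strain rps22a (4659), and 214% and 257% in rps22a/+ rps22b/+, where RPS22A was at 56.2% and 55.7%. RPS28B was at 182% and 145% in rps28a. RPL26B in rpl26a (105% and 97.3%), RPL40B in rpl40a (110% and 104%) and RPS25A in rps25b (100.3% and 91.5%) lay within the range of the other strains. RPL40A in rpl40b mRNA lay just under it, at 91.8%.

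**Figure D1:**
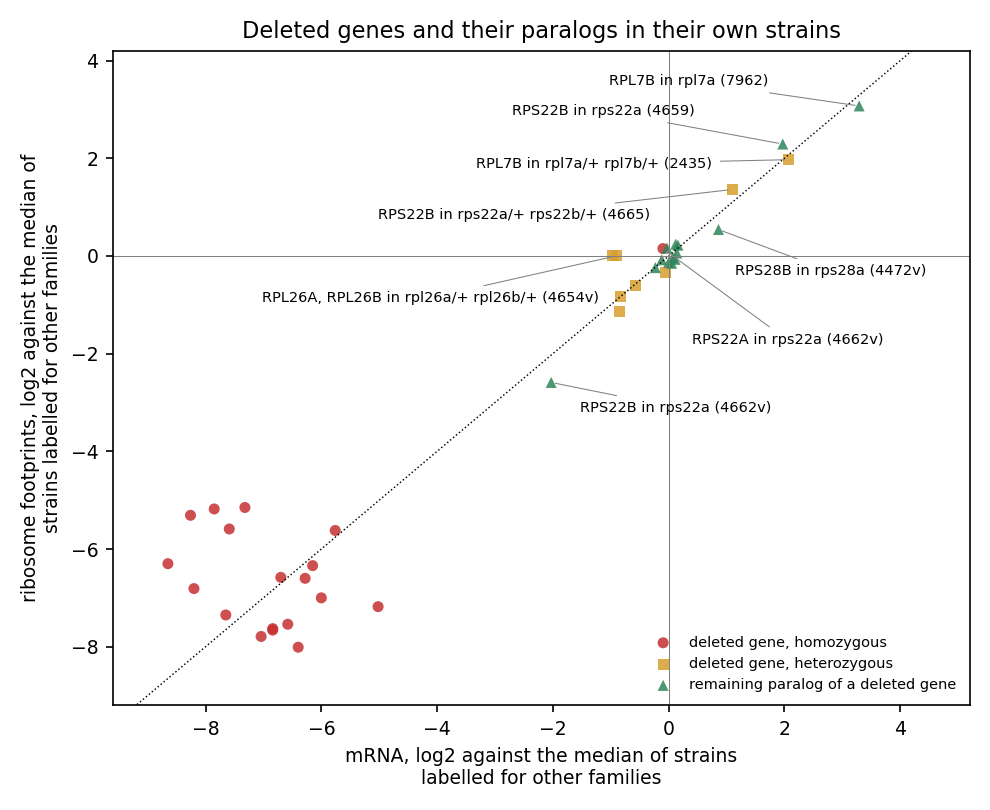
Level of each deleted gene and of its remaining paralog in its own strain, as log2 of mRNA (horizontal axis) and of ribosome footprints (vertical axis) against the median of strains labelled for other families, with 1 library per point and assay and RPL41A and RPL41B left out because they had no footprint reads. Homozygous deletions lie between -5 and -9 on both axes except RPS22A in the strain labelled rps22a (4662v), and RPL7B and RPS22B lie above 1 in several strains.

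In 3 strains a gene named in the genotype stayed near its usual level. In the strain labelled rps22a (4662v), RPS22A was at 93.4% of the other strains' median in mRNA and 111% in footprints, within the range of those strains, and RPS22B at 24.3% and 16.5%. In the footprint library labelled rpl26a/+ rpl26b/+ (4654v), RPL26A stood at 99.9% and RPL26B at 101%, whereas the mRNA library of that label had 53.1% and 51.2%. The same footprint library held RPS0A at 1.0% of the median of the other libraries, with 83 reads. In the strain labelled rpl40a/+ rpl40b/+ (3654v), RPL40B was at 55.3% in mRNA and 45.4% in footprints, and RPL40A at 96.4% and 79.3%. These libraries stayed in the class that their labels gave.

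The first question was how the transcriptomes of strains short of 40S proteins differed from those of strains short of 60S proteins. RPS9A (YPL081W), the minor copy of a 40S protein gene pair, showed the largest difference, with 120.6 ± 154.8 RPKM in RPS strains (SD, n = 9) and 518.4 ± 208 in RPL strains (n = 14), a log2 change of -2.65 ± 0.37 (SE). The cell wall mannoprotein genes CWP2 (log2 -1.41) and CWP1 (-1.25), the glucose-repressed hexokinase HXK1 (-1.36), the mitochondrial aldehyde dehydrogenase ALD4 (-1.33) and the lactate dehydrogenase CYB2 (-1.22) fell in RPS strains. TMA10 (-2.18), RCK1 (-1.52), MIN6 (-1.75) and the methionine pathway gene MET2 (-1.21) also fell. These genes lay near or below 10 RPKM in RPS strains, whose mRNA libraries were shallower. Their means there were 4.892 ± 5.685 RPKM (TMA10), 9.12 ± 2.79 (RCK1), 13.1 ± 14.9 (MIN6) and 8.93 ± 7.60 (MET2). In RPL strains the means were 17.2 ± 9.78, 35.4 ± 25.1, 22.8 ± 8.17 and 18.25 ± 4.75. The largest rises were those of HXT1, a low-affinity glucose transporter (log2 0.88, from 22.9 ± 7.17 to 42.8 ± 12.6 RPKM), the mitochondrially encoded ribosomal protein VAR1 (0.77), the ribosomal protein genes RPL9B (0.72) and RPL18B (0.60), the ADP/ATP carrier AAC3 (0.68) and the zinc transporter ZRT1 (0.67). FCY21 (0.58), the sterol transporter AUS1 (0.51), REF2 (0.46) and the potassium transporter TRK2 (0.46) completed the largest rises.

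In all, 493 of 5103 genes passed limma's test with Benjamini-Hochberg adjustment, 149 higher and 344 lower in RPS strains, and 19 of them changed by 1 or more in log2. Each gene named above lay on the called side of the RPL median in 7 to 9 of the 9 RPS strains, with adjusted p from 0.000189 (RPS9A) to 0.0494 (MIN6). Some calls depended on single libraries: of 25 removals of 1 library, VAR1 passed in 9, MIN6 in 5, RPS27A in 8, RPA135 in 5, PRE7 in 5 and VTC3 in 8. The direction of the whole was set in part by scaling: with median-of-ratios scaling 259 genes were higher and 322 lower, and with quantile normalization 318 and 293. Without the strain rps25a rps25b, which stood apart within its class, 874 genes passed, and without the strain labelled rps22a (4662v) 484 did.

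Genes of mitochondrial energy metabolism were lower in RPS strains as groups. Of 35 genes of oxidative phosphorylation, 27 fell and none rose, and 34 fell when adjusted over the list alone. They were led by ATP14 (log2 -0.62), the succinate dehydrogenase subunit SDH2 (-0.61), the NADH dehydrogenase NDI1 (-0.52) and the cytochrome bc1 subunit QCR9 (-0.52), and the median of the list was -0.35. Of 67 mitochondrial ribosomal protein genes, 18 fell (36 adjusted over the list alone), among them MRPL50 (-0.61) and MRPL31 (-0.48), while VAR1, encoded in the mitochondrial genome and not in this list, rose. Of 14 genes of the tricarboxylic acid and glyoxylate cycles, 6 fell (10 adjusted over the list alone), led by the isocitrate lyase ICL1 (-0.68) and LSC2 (-0.60). Camera with its preset correlation called these 3 lists lower (adjusted p = 1.41e-18, 9.37e-13 and 8.56e-05). Adjusted p = 0.256, 0.287 and 0.515 with an estimated correlation, so that none of the calls held.

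All 8 core histone genes fell, from HTA1 (log2 -0.60) and HHF1 (-0.48) to a list median of -0.43, and all 8 also fell when adjusted over the list alone. Of 23 genes in the list of chaperones that depend on the heat shock factor Hsf1, 13 fell (18 adjusted over the list alone), with the chaperones HSP42 at -0.86, SSA1 at -0.79 and HSP82 at -0.78 and with MBF1, a transcriptional coactivator and not a chaperone, at -0.90. The induced part of the environmental stress response had a median of -0.43, and 4 of its 36 measured genes fell (9 adjusted over the list alone): HXK1, ALD4, HSP42 and the superoxide dismutase SOD2 (-0.49). Of 33 proteasome genes, 4 fell, led by PRE5 (-0.56) and PRE7 (-0.34), and the same number adjusted over the list alone. Camera with its preset correlation gave adjusted p = 3.44e-10 for the histones, 5.02e-10 for the Hsf1 list, 5.33e-06 for the stress response and 7.09e-05 for the proteasome. Adjusted p = 0.256, 0.256, 0.531 and 0.535 with an estimated correlation.

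The lists of genes for cytosolic ribosomes and their assembly had medians between 0.05 and 0.13, and fry called none of them. After removal of the families deleted in any strain, 12 of 70 genes of 60S proteins rose and 1 fell (16 and 1 adjusted over the list alone), with RPL4B at 0.41 and the stalk protein RPP0 at 0.34. Among 47 genes of 40S proteins, 8 rose and 6 fell (11 and 6 adjusted over the list alone), and those that fell included RPS9A, RPS27A (-0.34), RPS9B (-0.32) and RPS3 (-0.29). The list of 40S genes had a median of 0.06 and a mean of -0.01, which differ in sign because of RPS9A and the other genes that fell. Of 58 assembly factors of the 40S subunit, 4 rose (4 adjusted over the list alone), RRP9 (0.31), PWP2 (0.28), UTP4 (0.27) and UTP22 (0.22), and the list median was 0.13. Among 72 factors of the 60S subunit, SQT1 rose (0.22) and SDO1 fell (-0.33), with a list median of 0.12 and no gene past the test adjusted over the list alone. Of 14 genes of RNA polymerase I, RPA190 (0.23) and RPA135 (0.23) rose, 2 also adjusted over the list alone. Of 26 initiation factors 3 rose (6 adjusted over the list alone): TIF3 (0.23), TIF4631 (0.21) and the poly(A)-binding protein PAB1 (0.20). Of 24 genes of ergosterol synthesis 3 rose, with ERG1 at 0.35, and ERG4 fell (-0.27), with the same counts adjusted over the list alone. The preset correlation called these 7 groups and the phosphate regulon (VTC3 0.44, VTC4 0.33) higher, and adjusted p lay between 0.287 and 0.535 for all of them with an estimated correlation.

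Fry, which asks whether the genes of a list move on balance one way, called 6 of the 25 lists in this comparison: oxidative phosphorylation, mitochondrial ribosomal protein genes, Hsf1-dependent chaperones, core histones, the tricarboxylic acid cycle and, upward, ergosterol synthesis. Lists not called by camera included glycolysis (3 of 17 genes fell: GPM1 -0.41, TDH3 -0.39 and TPI1 -0.27), amino acid synthesis under Gcn4 (1 of 36 past the test, GCN4 itself, -0.15), the unfolded protein response (KAR2 -0.36, CNE1 0.25), the iron regulon (ISU2 -0.46, ENB1 -0.41) and purine synthesis (SHM2 -0.32). Elongation factors (EFB1 -0.21), ribosome-associated chaperones (0 of 18 past the test), mating genes (0 of 3), early meiotic genes (0 of 1) and the strain marker genes (0 of 6) were not called either. RPS0A, of a family deleted in rps0b and therefore reported apart, rose by 0.15 (8 of 9 strains). Histone, SSA, HSP82, TDH, hexokinase and ribosomal protein genes have near-identical copies, so their values are uncertain where reads could not be assigned to a single copy.

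**Figure D2:**
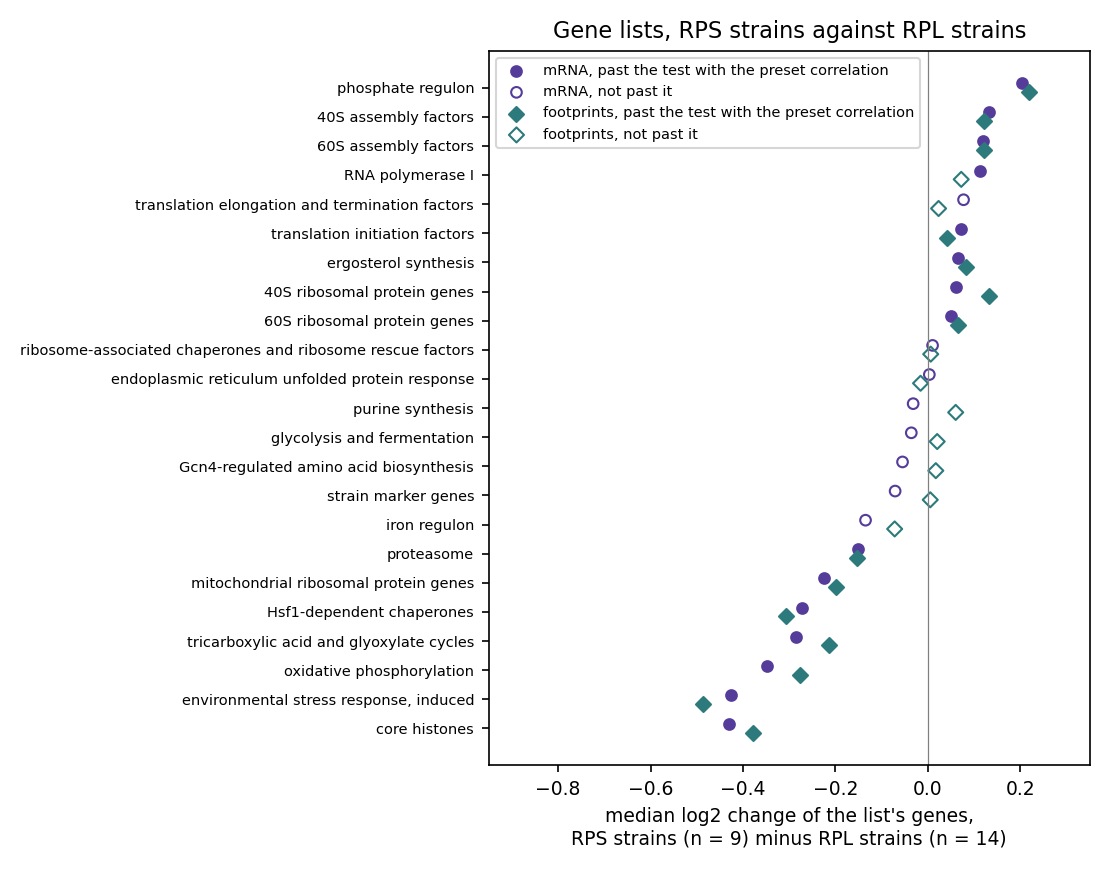
Median log2 change of the genes of each of 23 lists (RPS strains minus RPL strains, horizontal axis) in mRNA (circles) and footprints (diamonds), with filled symbols for lists past camera's test with the preset correlation. Core histones and the induced stress response lie lowest in both assays, and no list passed with an estimated correlation.

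In ribosome footprints, which count ribosomes on each coding sequence, 235 of the 4199 genes tested in both assays passed, 447 passed in mRNA and 127 in both, each of these in the same direction in both assays (19 higher and 108 lower in RPS strains). RPS9A fell again (log2 -2.21 ± 0.46 SE, from 624.6 ± 257.5 to 182.2 ± 206.9 RPKM), as did CWP2 (-1.36), CWP1 (-1.21), ALD4 (-1.21), HXK1 (-1.11), CYB2 (-0.94) and MET2 (-0.90). The glucose transporter HXT4 (-1.17), the glucose-signalling repressor MTH1 (-0.98) and the small heat shock protein HSP42 (-0.92) were among the 10 largest falls. Ribosomal protein genes of the 60S subunit led the rises: RPL9B (0.79), RPL8A (0.71), RPL18B (0.64) and RPP2B (0.54, from 6856 ± 1869 to 9608 ± 689.3 RPKM). ERG28, of ergosterol synthesis, rose by 0.64, the inositol monophosphatase INM1 by 0.55, SPO73 by 0.49, the oxidoreductase OYE2 by 0.46, AAC3 by 0.45 and SCM4 by 0.43.

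By limma, 237 of 4222 genes passed at an adjusted p under 0.05, 51 higher and 186 lower in RPS strains, with adjusted p from 0.00261 for SCM4 to 0.0495 for MTH1 among the named genes. Each named gene lay on the called side of the RPL median in at least 7 of 9 RPS strains, which the rule for the largest changes required. Of 25 removals of 1 library, RPL18B passed in 7, OYE2 in 12, HSP42 in 10, HSP104 in 6, RPS19A in 10, RPS26A in 11 and RPS29A in 5, and MTH1 passed in 7 of 20. The split was 93 and 127 with median-of-ratios scaling, 111 and 123 with quantile normalization, and 61 and 106 when libraries were rescaled without ribosomal protein genes. The count was 463 without the footprint library labelled rpl26a/+ rpl26b/+, 608 without rps25a rps25b and 57 without rps0b.

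The same lists were read in footprints. Of 70 genes of 60S proteins, 19 rose (26 adjusted over the list alone) and none fell. Of 47 genes of 40S proteins, 5 rose and 1 fell (20 and 1 adjusted over the list alone), with RPS27B at 0.40, RPS19A at 0.37 and RPS26A at 0.29. In the list of Hsf1-dependent chaperones 12 of 21 genes fell (16 adjusted over the list alone), with MBF1 at -0.88 and SSA1 at -0.79, and 7 of 8 core histone genes fell (8 adjusted over the list alone), led by HHF1 (-0.54) and HTA1 (-0.52). Oxidative phosphorylation had 12 of 35 genes lower (24 adjusted over the list alone), with COX7 at -0.57 and ATP15 at -0.56. Among mitochondrial ribosomal protein genes 10 of 67 fell (38 adjusted over the list alone), with MRP2 at -0.49, and LSC2 (-0.61) led the 3 of 13 that fell in the tricarboxylic acid cycle (5 adjusted over the list alone). The induced stress response had 4 of 30 lower (11 adjusted over the list alone), with HSP104 at -0.59 beside the 3 genes named above. No assembly factor of either subunit passed (0 of 58 and 0 of 72 by limma, and 0 adjusted over the list alone), with list medians of 0.12 and 0.12. ERG28, ERG1 (0.26) and ERG7 (0.25) rose among 24 genes of ergosterol synthesis (5 adjusted over the list alone), and RPS29A, of a deleted family reported apart, rose by 0.21. Camera called 14 of 23 lists with the preset correlation. None held: adjusted p = 0.281 or more with an estimated correlation. Fry called 5, namely 40S proteins, mitochondrial ribosomal proteins, Hsf1-dependent chaperones, oxidative phosphorylation and core histones.

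**Figure D3:**
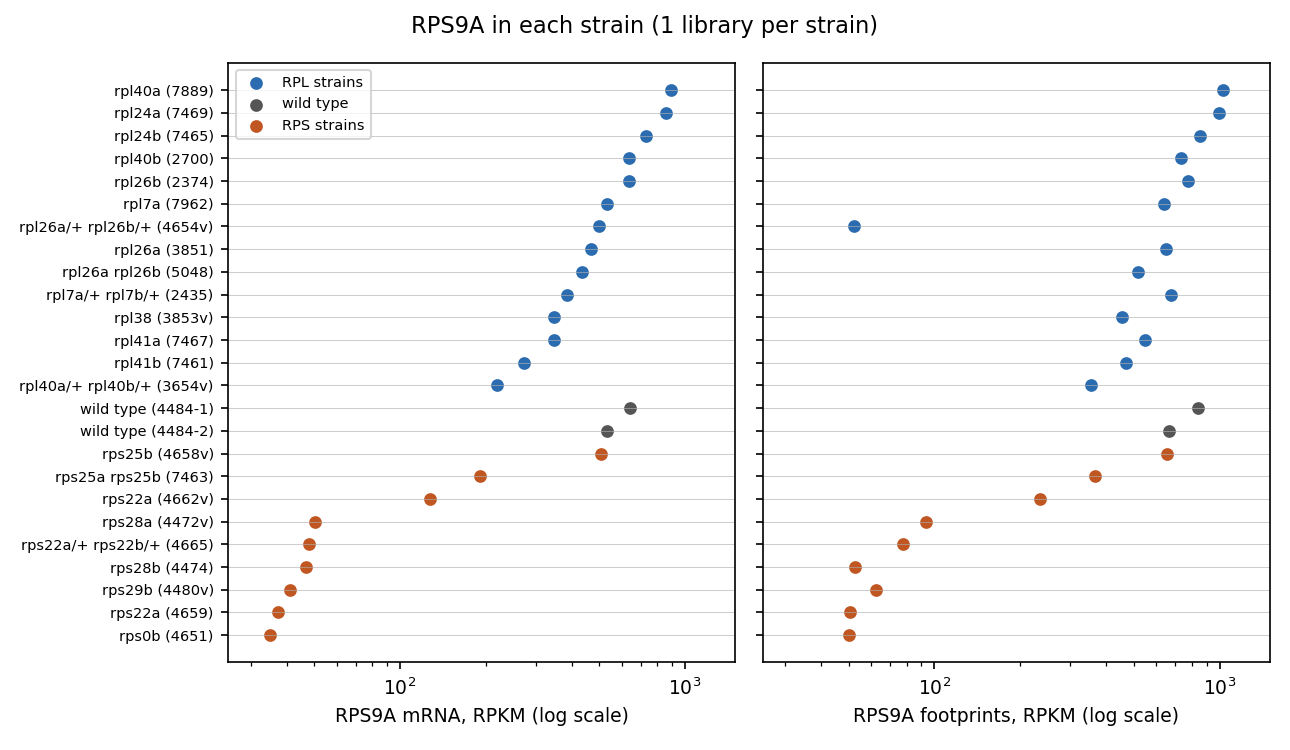
RPS9A level in every strain (RPKM, log scale) in mRNA (left) and footprints (right), with 1 point per library, grouped as RPL strains (n = 14), wild type (n = 2) and RPS strains (n = 9). In mRNA the RPS strains lie between 35.1 and 508.7, with rps25b the highest, and in footprints the library labelled rpl26a/+ rpl26b/+ lies at 52.1, away from the other RPL strains.

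Translational efficiency, the footprint level over the mRNA level of the same strain, differed in fewer genes. The largest rises in RPS strains were those of VPS20, a component of the endosomal sorting machinery (log2 0.81 ± 0.20 SE), NCE101 (0.81), SPO73 (0.80), MAK31 of an N-terminal acetyltransferase (0.68) and the proteasome subunit PRE5 (0.68). Only 5 genes fell: the transcription initiation factor SUA7 (-0.43), the phosphatase PPH22 (-0.34), PRS1 (-0.30), RVS167 (-0.27) and the initiation factor eIF4G gene TIF4631 (-0.19). Several of the genes that rose had less mRNA and little change in footprints, such as GPM1 (mRNA -0.41, footprints 0.20, efficiency 0.61), PRE5 (-0.56, 0.12, 0.68), RPS9B (-0.32, 0.16, 0.49), RPS3 (-0.29, -0.02, 0.27), ATP14 (-0.62, -0.17, 0.44) and MRPL16 (-0.47, 0.10, 0.57). TIF4631 had more mRNA (0.21) and a footprint change of 0.02.

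By limma, 47 of 4199 genes passed, 42 higher and 5 lower in RPS strains, and none changed by 1 or more in log2. Of 17 genes of glycolysis and fermentation, 4 rose (9 adjusted over the list alone), GPM1, FBA1 (0.29), TDH3 (0.28) and HXK2 (0.27), and the list was called by camera (adjusted p = 1.44e-06; adjusted p = 0.312 with an estimated correlation) and by fry (adjusted p = 0.0137). Genes of 60S proteins (1 of 70 past the test, RPL15A 0.29), 40S proteins (2 of 47) and oxidative phosphorylation (2 of 35, ATP14 and ATP2) were called higher with the preset correlation, and adjusted p was 0.914, 0.876 and 0.721 with an estimated correlation. When all 50 libraries were fitted without pairing the assays of a strain, 3 genes passed. The count was 85 without the footprint library labelled rpl26a/+ rpl26b/+, 25 without the strain labelled rps22a (4662v) and 11 without rps22a/+ rps22b/+. Of 25 removals of 1 strain, VPS20 passed in 10, PRS1 in 5, RPL15A in 7, FBA1 in 7 and TDH3 in 9.

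Each class was then set against wild type, where no single gene passed in the planned fit and gene groups are given by their medians. In RPS strains, the mRNA of mitochondrial ribosomal protein genes had a median log2 change of -0.34, lower in 67 of 67 genes, oxidative phosphorylation -0.39, lower in 35 of 35, and core histones -0.45, lower in 8 of 8. Adjusted p = 0.299 with an estimated correlation for each of the 3 lists. When adjusted over the list alone, 1, 10 and 7 of their genes passed. In footprints the lists stood at -0.35, -0.28 and -0.40, and 25, 1 and 4 genes passed adjusted over the list alone. The induced stress response of RPS strains had medians of -0.41 and -0.53 (adjusted p = 0.816 and 0.777 with an estimated correlation), and the wild-type libraries themselves lay 0.29 and 0.34 to either side of their mean on its score. In RPL strains, Hsf1-dependent chaperones stood 0.18 higher in mRNA (23 of 23 genes higher) and 0.25 higher in footprints (21 of 21), and mitochondrial ribosomal protein genes stood at -0.08 and -0.14. Adjusted p = 0.913 for both lists in mRNA and 0.604 in footprints with an estimated correlation. Camera with its preset correlation called 4 lists in mRNA, 7 in footprints and 5 in translational efficiency of RPL strains, and 10, 9 and 0 in RPS strains. Fry called none, and the lowest adjusted p was 0.299 with an estimated correlation.

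With limma, 0 of 5103 genes passed in mRNA of RPL strains against wild type (137 at an unadjusted p under 0.05) and 0 in RPS strains (521). In footprints 0 of 4222 passed in either class (109 and 404 unadjusted), and in translational efficiency 0 of 4199 (176 and 314 unadjusted). Voom on the recovered reads also gave 0 for mRNA and footprints, but with array weights 43 genes passed in mRNA and 320 in footprints of RPS strains. Only 2 wild-type libraries entered, and on simulated mRNA data of this size the test recovered 47.8% (RPL) and 50.7% (RPS) of changes of 0.58 and 82.1% and 77.6% of changes of 1. For translational efficiency these shares were 19.4% and 19.4%, and 61.2% and 68.7%, so most simulated changes of 0.58 were missed there. The simulated noise was independent between the assays of a strain, whereas their real deviations correlated at 0.28 to 0.87 in 24 of 25 strains. The shares for translational efficiency may therefore not hold for these data.

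The balance between 60S and 40S protein genes, taken per strain as the difference of their median log2 levels over 70 and 47 genes, did not separate the classes. In mRNA it was -0.10 ± 0.05 in RPL strains (SD, n = 14) and -0.12 ± 0.07 in RPS strains (n = 9), a difference of -0.02 (exact permutation test over 817190 splits, two-sided, p = 0.395). In footprints it was 0.07 ± 0.07 and 0.04 ± 0.08, a difference of -0.04 (exact permutation p = 0.271). The wild-type libraries lay at -0.15 and -0.05 in mRNA and at 0.08 and 0.09 in footprints. Taken as means over genes, the difference turned to 0.09 in both assays (exact permutation p = 8.69e-05 and 0.000914), and without RPS9A to 0.03 and 0.04 (exact permutation p = 0.00481 and 0.0208).

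Each mutant strain was also scored, as the median log2 change against the wild-type mean, for ribosomal protein genes (117), assembly factors (130) and the induced stress response (36 genes in mRNA, 30 in footprints). Strains with higher ribosomal protein gene scores had lower stress response scores, with r = -0.72 (permutation p = 0.0001) and rho = -0.67 (permutation p = 0.00063) in mRNA of the 23 strains. In footprints r was -0.81 and rho -0.83, both with p = 1e-05, the smallest that 100000 permutations can give. In footprints r was -0.66 within RPL strains (permutation p = 0.0108, n = 14) and -0.82 within RPS strains (exact permutation p = 0.00641, n = 9, with rho = -0.62, exact permutation p = 0.0857), and without the 2 strains farthest out, rpl7a and rps0b, r was -0.75. The RPL strains here include the footprint library labelled rpl26a/+ rpl26b/+. It had their highest ribosomal protein gene score (0.051) and lowest stress response score (-0.645), and r within RPL strains was not computed without it. In mRNA r was -0.68 without rps0b and rps29b, -0.40 within RPL strains (permutation p = 0.163) and -0.79 within RPS strains (exact permutation p = 0.0164; rho = -0.40, exact permutation p = 0.291). The relation within RPS strains leaned on rps25a rps25b, without which r was -0.45 in mRNA (exact permutation p = 0.273, n = 8) and -0.60 in footprints (exact permutation p = 0.129).

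Assembly factor scores fell as stress response scores rose among RPS strains (r = -0.91 in mRNA, exact permutation p = 0.00182; r = -0.95 in footprints, exact permutation p = 0.000118; n = 9), and without rps25a rps25b r was -0.83 and -0.93 (exact permutation p = 0.017 and 0.00107). Among the 14 RPL strains r was 0.24 (permutation p = 0.404) and 0.01 (permutation p = 0.967), with rho of 0.27 and -0.20. The difference between the classes was not tested. Over all 23 strains r was -0.54 (permutation p = 0.00803) and -0.59 (permutation p = 0.0032), rho was -0.48 (permutation p = 0.0201) and -0.60 (permutation p = 0.00329), and r was -0.50 and -0.57 without rps25a rps25b and rpl41a. Ribosomal protein genes and assembly factors gave r = 0.55 and 0.46 over all strains (permutation p = 0.00685 and 0.0276) and rho = 0.54 and 0.54 (permutation p = 0.0083 and 0.00937). Within RPS strains r was 0.81 and 0.87 (exact permutation p = 0.0127 and 0.00283) and rho 0.63 and 0.72 (exact permutation p = 0.076 and 0.0369), and r was 0.59 and 0.72 without rps25a rps25b (exact permutation p = 0.13 and 0.049). Within RPL strains r was -0.10 and -0.21, with rho of -0.07 and 0.13. Without the 2 strains farthest out r was 0.43 and 0.37 over all strains, past the threshold in neither assay (permutation p = 0.0509 and 0.0982). Over the 6 relations, adjusted p lay between 6e-05 and 0.0276.

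**Figure D4:**
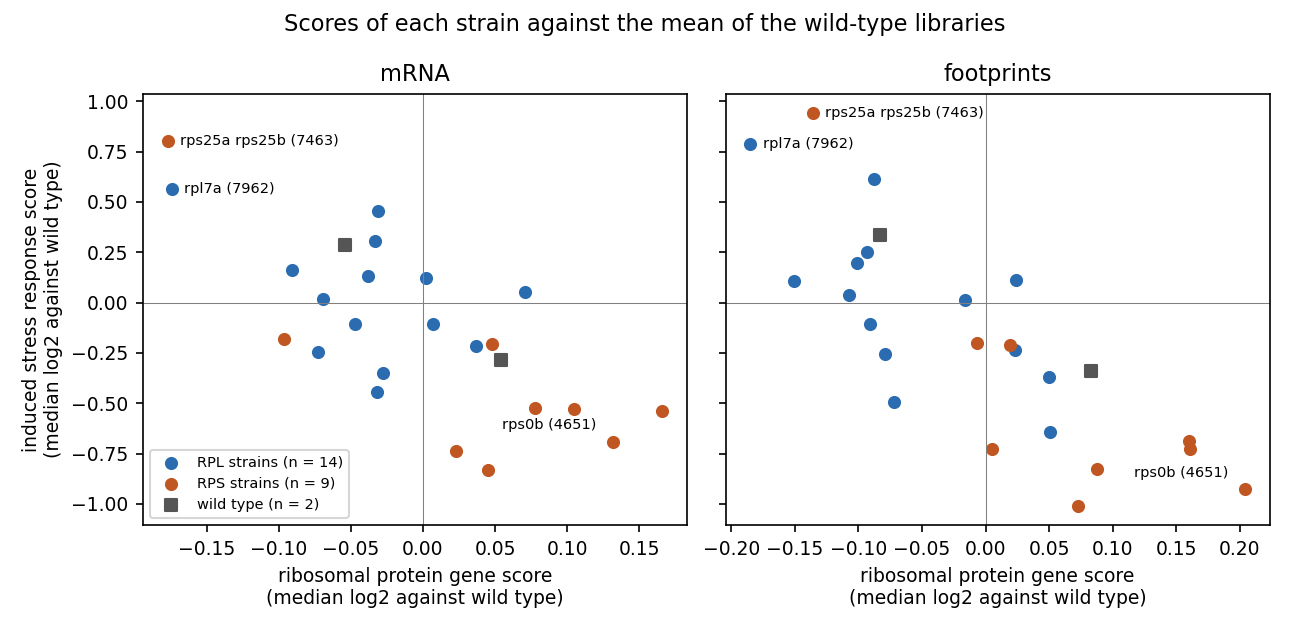
Induced stress response score (vertical axis) against ribosomal protein gene score (horizontal axis) of each strain, both as the median log2 change against the mean of the wild-type libraries, in mRNA (left) and footprints (right). Most RPS strains (n = 9) lie at the lower right, whereas rps25a rps25b has stress response scores of 0.80 and 0.94 and rps22a (4662v) has ribosomal protein gene scores of -0.10 and -0.01, RPL strains are n = 14, and the squares are the 2 wild-type libraries, which lie on opposite sides of 0 because their mean is the reference.

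Genes changed by 1 or more in log2 against the wild-type mean were counted per strain, with 103 genes of 5103 in mRNA and 36 of 4222 in footprints differing that much between the 2 wild-type libraries themselves. In mRNA RPL strains had a median of 78 such genes, from 44 in rpl38 to 184 in rpl41a, and RPS strains a median of 142, from 101 in rps28a to 268 in rps25a rps25b. In footprints the medians were 41.5 and 86, from 16 in rpl38 to 228 in rps25a rps25b. Over the 23 mutant strains, those with more mRNA reads had fewer such genes (rho = -0.81, permutation p = 1e-05), while within RPL strains rho was -0.447 (permutation p = 0.111) and within RPS strains -0.435 (exact permutation p = 0.242). In footprints rho was -0.30 (permutation p = 0.171). With the reads of every library thinned to the smallest total the medians were 125.5 (RPL) and 185 (RPS) in mRNA, where rho was still -0.65, and 46 and 91 in footprints (class means apart by 65.3 and 51.8, exact permutation p = 0.00113 and 0.000901), with 157 and 34 genes apart by that much between the wild-type libraries. No nuclear chromosome was shifted by 0.3 or more in both assays in any strain, and the nuclear medians lay between -0.05 and 0.06 in mRNA and between -0.08 and 0.10 in footprints. The median level of mitochondrially encoded genes, with 18 kept in mRNA and 1 in footprints, was higher in rpl38 (0.54 and 0.38) and lower in rpl24b (-0.38 and -1.10) and rps25a rps25b (-0.39 and -0.67). The 1 gene in footprints also varied widely in strains not listed, such as rpl26a (1.67) and wild type 4484-2 (-1.29), so its direction carries little weight.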

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

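The tests chosen after the results were seen are the label test of the footprint library labelled rpl26a/+ rpl26b/+, the tests on RPS9A and the class differences of strain scores; the others were set beforehand.

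The strain rps25a rps25b stood apart from the other RPS strains. Its induced stress response score was 0.80 in mRNA, where the other 8 RPS strains lay between -0.83 and -0.18, and 0.94 in footprints, where they lay between -1.01 and -0.20. It had 228 genes changed by 1 or more in log2 in footprints, against 47 to 131 in the others. Of 14 groups of strain values examined for a far sample, 3 had one, and chance gives about 0.7. All 3 were this strain, whose assays correlated at 0.87, so they are not independent and 3 against 0.7 overstates the excess. No explanation was tested.

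The ribosomal protein gene score in footprints was higher in RPS than in RPL strains by 0.12 (exact permutation p = 0.00404, adjusted over 6 scores p = 0.0242), with 8 of 9 RPS strains above the RPL median. The wild-type libraries lay 0.08 to either side of their mean on that score. In mRNA the difference was 0.07 (adjusted exact permutation p = 0.0811), and assembly factor scores differed by 0.13 in both assays (adjusted exact permutation p = 0.194 and 0.276), none past the threshold. Without rps25a rps25b, ribosomal protein gene scores differed by 0.10 in mRNA and 0.15 in footprints, and assembly factor scores by 0.20 and 0.21. The stress response score differed by -0.41 in mRNA and -0.49 in footprints (RPS minus RPL class means, adjusted exact permutation p = 0.0596 for each), which failed the correction. Without rps25a rps25b it differed by -0.55 and -0.67 (unadjusted exact permutation p = 0.000241 and 0.000663). That strain was picked out on this same score and goes against the difference, so the smaller p-values follow from its removal and lend no support.

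The difference between RPS and RPL strains in mRNA (493 genes) was weighed first. Of 100 splits of the 23 mutant strains into 14 and 9, only the real one called as many genes (1 of 100, the smallest share possible, with the highest other at 2). A chance split of unrelated strains is argued against. It is not excluded, because the splits treat strains that share deleted genes as independent. mRNA libraries of RPS strains were shallower, but with every library thinned to 961794 reads, 67.7% of the genes kept their call and direction. The median size of change of the called genes was 0.34 before and 0.34 after, which is no evidence on depth because thinning keeps the expected level of each gene. The change between the classes rose with coding length (Spearman correlation 0.244). With the trend on coding length removed, 80.7% kept theirs, and the median size of change of the called genes went from 0.34 to 0.30. Depth and length as whole causes of the mRNA gene calls are argued against, while growth rate and any unlabelled batch of cultures stay open and untested. Neither depth nor length was tested for the calls in footprints or in translational efficiency, which takes in the mRNA values. The gene lists were not tested again without the length trend, so a part of length in the list results stays open. For footprints 2 of 100 splits called as many as the real 237 (highest other 294), and for translational efficiency 1 of 100 (real 47, highest other 6). A split that ignored the labels thus called more footprint genes than the labelled split, and the reason was not tested.

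The footprint library labelled rpl26a/+ rpl26b/+ was the second pattern. Its deviations correlated at -0.12 with those of its own mRNA library, while in the other strains the correlation lay between 0.28 and 0.87, and RPL26A and RPL26B stood at 99.9% and 101% of their usual level. RPS0A stood at 1.0%, where homozygous deletions had 0.36% to 2.79% in footprints, with RPS0B at 112%, RPS9A at 9.77% and RPS22B at 12.8%, and the closest other footprint library was rps0b (0.58). Low depth is argued against: the library held 4.133 M reads, and the shallowest other, rps22a (4662v) with 4.102 M, correlated at 0.643 with its own mRNA library. A mislabelled sample may explain these values, which are as in a strain lacking RPS0A, a deletion that no label names.

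RPS9A in RPS strains was the third pattern. Reads passed between paralogs are argued against in mRNA, since RPS9B mRNA was also lower (-0.32). In footprints RPS9B differed by 0.16 (adjusted p = 0.196) and the sum of both genes was 5418 ± 611.7 RPKM in RPL and 5501 ± 498.2 in RPS strains (SD, exact permutation p = 0.733), so that reads passed between paralogs and a separate change of each gene cannot be told apart there, because the rise of RPS9B missed the threshold. A sequence variant carried by some strains would leave 2 separate groups of strains, but the largest gap between neighbouring strains was 28.6% of the log2 range, between 50.2 and 127.3 RPKM with 6 strains below it, which neither shows nor excludes such a variant. A variant and a response to 40S deficiency therefore cannot be told apart for RPS9A in these strains, because the largest gap lies between the bounds of 25% and 50% of the range set for that test.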

How the results depend on the processing

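Chosen after the data were seen were voom, the deposited values, removal of the footprint library labelled rpl26a/+ rpl26b/+ and of the strains labelled rps22a (4662v) and rps25a rps25b, 2 forms of the balance, score relations within RPS strains without rps25a rps25b, and thinned reads for genes changed per strain.

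For mRNA of RPS against RPL strains (493 genes) array weights gave 947, removal of the strains with a listed chromosome 776 and removal of rps25a rps25b 874, and voom gave 502. Removing 1 library gave 333 (rps0b) to 874. For footprints (237) array weights gave 1297, removal of double heterozygotes 475, of strains with a listed chromosome 435, of the library labelled rpl26a/+ rpl26b/+ 463 and of rps25a rps25b 608, the deposited values gave 146 and voom 219. Removing 1 library gave 57 to 608 in footprints: rpl38 155, rpl41a 387, rpl26b 142, rpl26a rpl26b 124, rpl24b 136, rpl40b 105, rpl40a 123, rpl24a 106, rpl7a 106, rps28a 139, rps22a/+ rps22b/+ 98, rps29b 99, rps22a (4659) 68, rps28b 116 and rps0b 57. For translational efficiency (47) median-of-ratios scaling gave 29 (26 higher), no trend 22, array weights 133, removal of double heterozygotes 149, of strains with a listed chromosome 13, of the library labelled rpl26a/+ rpl26b/+ 85 and of rps22a (4662v) 25. Without the strain block, that is without pairing the assays, 3 genes passed, and 0 in either class against wild type. Removing 1 strain gave 11 to 85: rpl40a/+ rpl40b/+ 84, rpl26b 30, rpl26a rpl26b 20, rpl24b 17, rpl40b 17, rpl40a 17, rpl24a 14, rpl7a 14, rps28a 22, rps25b 77, rps22a/+ rps22b/+ 11, rps29b 23, rps22a (4659) 13, rps28b 15 and rps0b 12. The causes were not tested.

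Against wild type the counts of 0 became, for RPL mRNA, 1 with a pseudocount of 0.1, 3 with no minimum level, 1 with array weights and 1 with only the 2 classes in the fit; removing 1 library gave 0 to 3 (wild type 4484-2 3, rpl40b 1, rps29b 1). For RPS mRNA they became 1 with no minimum level, 43 with array weights, 1 without the strains with a listed chromosome, 1 with only the 2 classes and 1 without rps25a rps25b; removing 1 library gave 0 to 1 (wild type 4484-2, rps25b, rps25a rps25b and rps29b). Array weights gave 320 for RPS footprints, and removing 1 library 0 to 1 (wild type 4484-2), while RPL footprints stayed at 0 (0 to 0). For translational efficiency of RPL strains a pseudocount of 0.1 and the fit of only 2 classes gave 1 each, and removing 1 library gave 0 to 1 in both classes (wild type 4484-2, rps29b). A lone wild-type library was assumed to vary like the other classes. The cause was not tested.

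List calls fell to 0 with an estimated correlation in every comparison that had any (translational efficiency of RPS strains against wild type had 0 with the preset correlation too). Fry gave 6, 5 and 1 for mRNA, footprints and translational efficiency of RPS against RPL strains and 0 against wild type. Quantile normalization gave 4 for footprints of RPL strains against wild type, and 2, 2 and 1 for translational efficiency (RPS against RPL, RPL and RPS against wild type).

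The balance difference reversed with means over genes (0.091 in mRNA, 0.086 in footprints), means without RPS9A (0.033, 0.036), all ribosomal protein genes kept (0.010, 0.029) and, in mRNA, medians of each gene's deviation (0.004). Removing 1 strain gave -0.036 to -0.010 and -0.051 to -0.020. Within RPL strains 5 score relations changed: the sign of r turned for ribosomal protein genes with assembly factors (-0.096, -0.206) and for assembly factors with stress response (0.243, 0.012), while the footprint rho of 0.134 and -0.196 kept the sign, and ribosomal protein genes with stress response in mRNA weakened (-0.395). Within RPS strains without rps25a rps25b, ribosomal protein genes with stress response weakened (-0.445, -0.599), as did ribosomal protein genes with assembly factors in mRNA (0.593). Ribosomal protein genes with assembly factors also weakened with median-of-ratios scaling (0.395, 0.250), with means over genes in footprints (0.263) and without the 2 farthest strains (0.432, 0.369). Genes changed per strain had medians of 40 (mRNA) and 31 (footprints) with a pseudocount of 10, and 7 pairs of strain and chromosome were listed at a threshold of 0.2, none of them nuclear. The cause was not tested.

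Of the 78 mRNA values of named genes, 2879 of 3169 alternatives kept direction and call and 290 lost the call. The numbers were 1584 and 325 of 1909 for 46 footprint values and 756 and 327 of 1083 for 26 values of translational efficiency, with none reversed. The 38 deleted-gene values below range were 38 with median-of-ratios scaling. Depth limits genes near 10 RPKM most, above all in mRNA of RPS strains (0.962 to 1.518 M reads).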

Other observations

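These values were chosen after the data were seen, and no explanation was tested for them. RPL22B, the minor copy of a 60S protein gene pair, had few footprints in 7 RPL strains, and in 5 of them its mRNA was also below the range of the other strains. Footprints were at 8.37 RPKM in rpl7a, 17.2 in rpl24a, 20.7 in rpl40a, 25.3 in rpl40b, 31.0 in rpl26b, 34.8 in rpl24b and 47.3 in rpl26a rpl26b. The remaining strains lay between 97.9 (rps0b) and 420.9 (rpl41a). RPL22B mRNA was at 86.9 RPKM in rpl40b, 103.2 in rpl40a, 125.4 in rpl24a, 126.4 in rpl7a, 127.1 in rpl26b, 153.9 in rpl26a rpl26b and 204.8 in rpl24b, and the remaining strains lay between 133.8 (rpl38) and 282.4 (rpl41a). Wild type had 219.6 and 207.8 in mRNA and 101.8 and 113.4 in footprints.

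RPS22B mRNA was low in 5 RPS strains, at 116.1 RPKM in rps28b, 138.1 in the strain labelled rps22a (4662v), 159.2 in rps0b, 177.1 in rps28a and 183.2 in rps29b, and at 392.7 in rps25a rps25b and 728.7 in rps25b. RPL strains lay between 398.6 (rpl24a) and 731.4 (rpl26a rpl26b), and wild type at 693.2 and 644.8.

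The amino acid synthesis genes ARG4 and HIS4, in the list of marker genes, varied widely between strains of both classes. ARG4 mRNA ranged from 50.9 RPKM in rps22a/+ rps22b/+ to 1086 in rps25a rps25b, with 55.3 in rpl7a and 659.3 in rpl41a, and HIS4 from 127.1 in rps0b to 1162 in rps25a rps25b. The wild-type libraries had 155.0 and 247.4 for ARG4.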
